A study of Mus musculus with 6 samples.

How the data were processed

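RNA was measured in cultures of male wild-type mouse aortic cells, named endothelial cells by the labels, in 3 Vehicle and 3 LPS libraries (500 ng/mL for 8 h). Per the labels' protocols, total RNA was extracted with TRIzol and sequenced as paired ends at Novogene. Reads were aligned with HISAT2 to GRCm38 (mm10), per the submitters' processing notes; the counting tool, its strand setting and the annotation release are not given in the sources used here. The deposited table holds raw counts per gene, as whole numbers that the authors had not normalised, with a gene length per gene, per the file headers. Without a known strand setting, reads of overlapping genes cannot be told apart, and genes with near-identical copies, such as Gapdh, H2-Q4 and Gm10800, are uncertain.

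The table held 54532 genes. Of the gene names, 27 had been turned into calendar dates, as spreadsheets do, and were restored from the gene IDs. GENCODE M21 held 99.774% of the gene IDs, and 98.106% of the genes had the same coordinates there. The columns of the LPS cultures carry the treatment in their names; the columns M1 to M3 without it were taken as Vehicle 1 to 3 by elimination. Counts summed to 17294955, 18696085 and 25082714 in Vehicle 1, 2 and 3 and to 20884944, 16509197 and 21149988 in LPS 1, 2 and 3. A count of 0 allows up to 3 counts, or 0.117 to 0.188 CPM depending on the library; such floors cover counting error only. CPM were computed with TMM-scaled library sizes. Counts of sex-linked genes were checked against the labels.

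The groups were compared with edgeR 4.0.16 in R 4.3.3, with TMM normalization, the filterByExpr filter by group (14508 genes kept) and the 2-sided quasi-likelihood F-test. P values were adjusted by the Benjamini-Hochberg method, and genes with adjusted p below 0.05 were called. The standard errors are those of the fitted log2 fold changes unless stated otherwise. SDs are between libraries of a group. The labels state that each number is 1 cell isolation shared by a Vehicle and an LPS culture, so the numbers pair the libraries. The deviations of paired libraries from their group means correlated across genes by 0.134, −0.0604 and 0.274 in isolations 1, 2 and 3 (genes are not independent replicates). The fit without the pairing was set as the main one before the data were examined, and the fit with the isolation as a replicate block as its alternative. Differences between isolations were tested by the F-test of both isolation coefficients in the model with isolation and group.

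Gene lists were tested with camera at a preset correlation of 0.01, adjusted over the 24 lists. These were nuclear factor kappa B, Toll-like receptors, type I interferon, interferon-inducible GTPases, chemokines, cytokines, leukocyte adhesion, endothelial identity, endothelial junctions, coagulation, vascular tone, glycocalyx, MHC class I, cell death, cell cycle, mesenchymal transition, basement membrane, oxidative stress, glycolysis, oxidative phosphorylation, cholesterol, Notch and angiogenesis, unfolded protein response, and immediate early genes. The 10 lists of markers of other cells (smooth muscle, pericyte, fibroblast, macrophage, lymphocyte, neutrophil, lymphatic, mesothelial and epithelial, adipocyte, red blood cell) were counted but not tested as sets. Lists, alternatives and the rule for named genes were fixed before the data were examined. The rule takes the 10 highest and 10 lowest fold changes among called protein-coding genes with a mean of at least 5 CPM and the same direction in all 3 isolations. It adds the 3 called members of each list with the largest fold change, the most abundant member of each list without a call, a fixed panel, and the pair of most abundant genes of each marker list. The text leaves out some list members to keep its length, and a few genes that the rule names are not reported here.

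Other settings set before the data were examined were DESeq2 size factors, library sizes alone, no filter, a stricter filter of at least 1 CPM in 3 libraries, protein-coding genes alone, DESeq2 1.42.0, limma-voom (limma 3.58.1), the replicate block in edgeR and in DESeq2, a threshold of 0.01, leaving out each library and each isolation, camera with an estimated correlation, and fry. After the data were seen, an offset for transcript length was added: in each library, a natural spline with 5 degrees of freedom was fitted to log2 deviations from the gene means over the log2 length of the longest GENCODE transcript, and entered the edgeR model as an offset. Also added were offsets for the deposited gene length and for length with GC content, the length offset with the replicate block or with an estimated correlation, the isolation test with the length offset, and a fit without the LPS libraries of isolations 2 and 3, in which the lone LPS library is assumed to vary like the other group. The median log2 fold change of all tested genes was −0.00306; with library sizes alone it moved by −0.0726 and with the length offset by 0.0473. Of the genes called, 50.57% were higher, 44.42% with library sizes alone and 61.99% with the length offset.

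The test was checked on simulated data. Without a length trend it recovered 76.92% of genes changed 2-fold and 52.38% of those changed 1.5-fold, and called 7 unchanged genes of 14103 tested. With a simulated length trend it called 2860 unchanged genes of 14125, and 7 with the length offset, which recovered 75.38% of genes changed 2-fold. The simulated trend was itself the spline fitted for the offset. This check therefore cannot tell how well the offset removes the trend of the real libraries. Camera called the simulated list and 0 of 50 random lists in a single draw of each. The simulated genes were drawn independently of each other, and the simulated list held only raised genes. This check therefore cannot support the calls of real lists whose genes vary together. Group differences of quality measures were tested with 2-sided exact permutation tests, in which 3 against 3 cannot go below 0.1.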

Results

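Gene expression was measured by bulk RNA sequencing in cultured cells from the aorta of wild-type male mice, which the labels name endothelial cells. The cultures were kept for 8 h in starvation medium alone (Vehicle, 3 libraries) or with 500 ng/mL lipopolysaccharide (LPS, 3 libraries), a component of the outer membrane of Gram-negative bacteria that is sensed through Tlr4. Each of 3 cell isolations gave 1 Vehicle and 1 LPS culture. Total counts per library ranged from 16509197 to 25082714, and 3 counts corresponded to between 0.117 and 0.188 CPM (counts scaled to a common library size). Of 54532 genes in the table, 14508 had enough counts to be tested. The comparison between the groups addresses which genes respond to LPS.

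Chemokine genes, whose products attract leukocytes, rose together under LPS. Of 14 tested chemokine genes, 12 rose and 2 were not called, the same numbers as adjusted over the list alone. Their median log2 fold change was 1.48 (camera adjusted p = 2.14e-14, and adjusted p = 0.0308 with an estimated correlation). Cxcl2, a neutrophil attractant (ENSMUSG00000058427, GRCm38 chromosome 5, 90903871 to 90905938), rose from 3.35 ± 0.903 to 34.7 ± 6.93 CPM (SD, n = 3 each). That was a log2 fold change of 3.39 (SE 0.215, edgeR adjusted p = 0.000169). Ccl5 rose from 0.445 ± 0.183 to 6.45 ± 0.976 CPM and Cxcl3 from 0.247 ± 0.0782 to 3.31 ± 0.842 CPM. Cxcl1 rose from 180 ± 11.5 to 474 ± 30.2 CPM, and Ccl2, a monocyte attractant, from 333 ± 41.8 to 1152 ± 240 CPM. Cxcl10, an interferon-inducible chemokine, rose by 2.10 on the log2 scale but stayed at a low 2.27 ± 1.08 CPM under LPS. Cxcl12, the most abundant chemokine gene without a call, had 3320 ± 76.5 CPM in Vehicle and 2884 ± 199 CPM under LPS (adjusted p = 0.111), and was called lower without the library LPS 1 (adjusted p = 0.0145). With an offset for transcript length in the model, 10 of the 14 chemokine genes were called higher; the offset with a replicate block called Cxcl12 higher (log2 fold change 0.22, adjusted p = 0.0336).

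Cytokine genes rose as a group. Of 13 tested, 8 rose and 5 were not called, also when adjusted over the list alone, with a median log2 fold change of 1.42, or 0.92 with the length offset. The camera adjusted p was 1.03e-05, with adjusted p = 0.283 with an estimated correlation. Il6, a central inflammatory cytokine (ENSMUSG00000025746, chromosome 5, 30013114 to 30019981), rose from 95.2 ± 19.9 to 518 ± 124 CPM, a log2 fold change of 2.44 (SE 0.194, adjusted p = 0.000419). Il11 rose from 9.21 ± 4.23 to 59.8 ± 46.3 CPM. The colony-stimulating factor gene Csf3 rose from 1.60 ± 0.400 to 9.34 ± 2.92 CPM, and Csf2 from 0.364 ± 0.171 to 4.93 ± 1.66 CPM. Csf1, the most abundant cytokine gene without a call, had 2250 ± 188 CPM in Vehicle and 2471 ± 86.2 CPM under LPS (adjusted p = 0.289), and was called higher with the length offset (adjusted p = 0.0171). Ifnb1, which encodes interferon beta, had 0 counts in all 6 libraries, which allows a level of up to 0.188 CPM in the shallowest of them and covers counting error only.

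**Figure D1:**
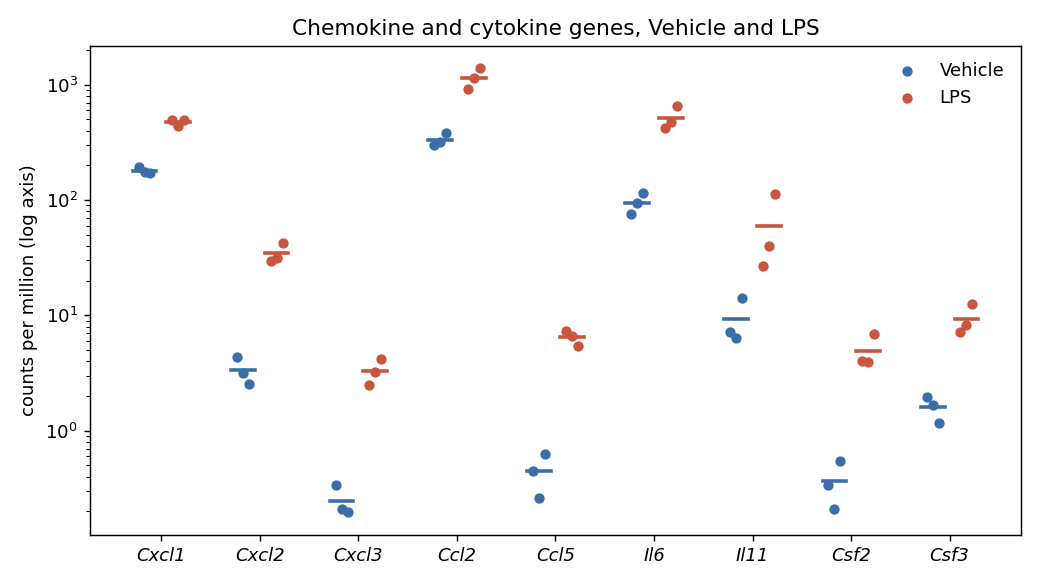
Expression in CPM (log axis) of 9 chemokine and cytokine genes in each of the 6 libraries, Vehicle in blue and LPS in red; points are libraries and bars are group means. Every LPS library lies above every Vehicle library for each gene, for example 34.7 against 3.35 CPM on average for Cxcl2.

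Across all genes, 3616 were called higher and 3534 lower under LPS (49.28% of those tested), of which 721 were at least 2-fold higher and 782 at least 2-fold lower. Among called protein-coding genes with a mean of at least 5 CPM and the same direction in all 3 isolations, the 10 highest fold changes included, besides Cxcl2, Il11, Csf3 and Il6, the opioid precursor gene Penk, the epidermal barrier gene Sprr2e, the natriuretic peptide gene Nppb, the growth factor gene Areg, the acute-phase gene Saa3 and Gm10800. Penk (ENSMUSG00000045573, chromosome 4, 4133531 to 4138819) rose from 67.5 ± 11.5 to 484 ± 175 CPM (log2 fold change 2.84, SE 0.239, adjusted p = 0.000454). Saa3 (ENSMUSG00000040026, chromosome 7, 46711998 to 46715700) rose from 28.6 ± 6.18 to 131 ± 3.69 CPM. Sprr2e, Nppb and Areg rose by 2.74, 2.66 and 2.43 on the log2 scale. Gm10800 had 1.93 ± 1.88 CPM in Vehicle and 21.1 ± 20.3 CPM under LPS, and its call ended without Vehicle 1 (adjusted p = 0.0564), in DESeq2 and in limma-voom; reads of such a repeat-like gene can be shared with other copies. The 10 lowest by the same rule were Zfp871, Gm38394, the copper transporter gene Atp7a, BC005561, Fam120c, 9930111J21Rik1, Pdpr, the lipid transfer gene Vps13c, Rbm41 and the corepressor gene Lcor, at −2.98 to −2.19 on the log2 scale. Their longest transcripts had 3728 to 11527 bases, and with the length offset their log2 fold changes lay between −2.25 and −1.48, at −2.25 for Zfp871 and −1.48 for Vps13c. Zfp871 (ENSMUSG00000024298, chromosome 17, 32771236 to 32788287) fell from 29.1 ± 5.22 to 3.62 ± 2.13 CPM (log2 fold change −2.98, SE 0.323, adjusted p = 0.00109), and Atp7a (ENSMUSG00000033792, chromosome X, 106027276 to 106124926) from 39.5 ± 6.23 to 7.30 ± 5.66 CPM. With the length offset, 3172 genes were called higher (61.99% of those called, against 50.57% without it) and 1945 lower, 330 at least 2-fold higher and 524 at least 2-fold lower. The offset takes the longest annotated transcript, which need not be the one expressed, so it can misjudge single genes. The ribosomal protein gene Rps15a, named after its value was seen, was given 5179 bases, against a median of 1100 for cytosolic ribosomal protein genes. Its log2 fold change was 1.26 without the offset and 1.64 with it. Of the calls without the offset, 2360 higher and 1656 lower ones were kept, 3070 ended and 64 were called in the opposite direction. The 2-fold counts depended on single libraries: 1204 higher and 1362 lower without LPS 1, 366 higher without LPS 3. Without isolation 2, edgeR called 8 higher and 0 lower genes, with 2587 and 2469 at an unadjusted p under 0.05, DESeq2 called 1543 and 1259, and edgeR with the replicate block 2322 and 2296; the 8 genes were Cxcl1, Cxcl2, Ccl5, Penk, Saa3, Procr, Sprr2e and Cxcl5, the last named after its value was seen.

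Fold changes under LPS fell with transcript length. In 10 bins of tested genes by transcript length, the bin of the shortest, with transcripts of 57 to 1084 bases, had a median log2 fold change of 0.73, and 49.8% of its genes were called higher. The bin of the longest, with transcripts of 6658 to 123179 bases, had a median of −0.68, and 72.1% were called lower. The slope of log2 CPM per doubling of transcript length was taken against the mean of the Vehicle libraries, or of the other Vehicle libraries where the library was itself Vehicle. It was −0.181, −0.304 and −0.351 in LPS 1, 2 and 3 and 0.00945, 0.0281 and −0.0375 in Vehicle 1, 2 and 3. The Vehicle slopes average 0 by construction, and slopes of the groups rest on unlike references. The group means were −0.279 ± 0.0878 and 0 ± 0.0338 (SD, n = 3 each; 2-sided exact permutation test, p = 0.1, the smallest p that 3 against 3 allows). The share of mitochondrially encoded counts was 1.94 ± 0.0482% in Vehicle and 1.43 ± 0.199% under LPS (exact p = 0.1). With the length offset the median of the longest bin was −0.0368 and that of the shortest 0.241, so the offset removed most but not all of the trend.

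**Figure D2:**
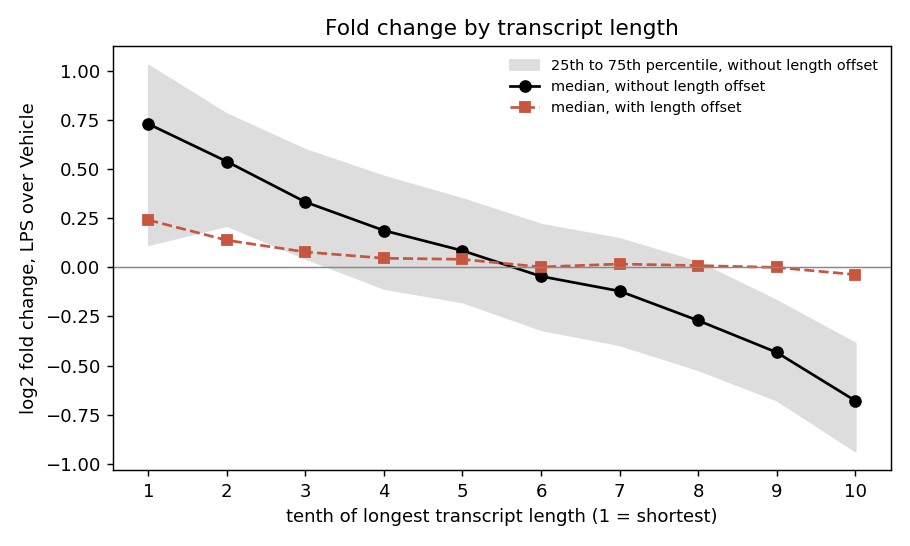
Median log2 fold change of LPS over Vehicle in 10 bins of tested genes ordered by the length of their longest annotated transcript, without an offset (black, with the 25th to 75th percentile in grey) and with the length offset (red squares). Without the offset the medians run from 0.73 in the shortest to −0.68 in the longest bin.

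Genes of nuclear factor kappa B signalling, the main transcription pathway downstream of LPS sensing, moved in both directions. Of 20 tested, 6 rose and 2 fell (5 and 1 adjusted over the list alone), and the list was not called (median log2 fold change 0.23, camera adjusted p = 0.159). It was called with the length offset (9 genes higher and 1 lower, camera adjusted p = 0.0377, adjusted p = 0.213 with an estimated correlation, and 0.0880 with the replicate block added). Nfkbia, the feedback inhibitor, rose by 0.73 on the log2 scale (SE 0.103, adjusted p = 0.00144), or 0.37 with the length offset. Nfkbib rose by 0.88, and the deubiquitinase gene Cyld, with a transcript of 8022 bases, fell by 0.90, or by 0.27 with the length offset. The feedback inhibitor Tnfaip3 fell by 0.32 (adjusted p = 0.0416); its log2 fold change was 0.16 with the length offset (adjusted p = 0.131), and its call ended without each of Vehicle 1, Vehicle 2, Vehicle 3, LPS 2 and LPS 3 (adjusted p up to 0.137). Among other inflammatory effectors, the superoxide dismutase gene Sod2 rose from 188 ± 2.34 to 318 ± 14.8 CPM, with a log2 fold change of 0.76, or 1.22 with the length offset. Ptgs2, the inducible cyclooxygenase, rose from 811 ± 72.9 to 1203 ± 60.6 CPM, and Nos2, the inducible nitric oxide synthase, from 27.3 ± 5.29 to 103 ± 37.2 CPM.

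The list of LPS sensors and Toll-like receptor signalling was not called (2 of 21 genes rose and 6 fell, the same adjusted over the list alone, and 3 and 2 with the length offset; camera adjusted p = 0.742). Tlr4, the LPS receptor, fell from 40.4 ± 2.09 to 22.4 ± 2.93 CPM, a log2 fold change of −0.85 (SE 0.117, adjusted p = 0.00144). Its coreceptor Cd14 rose from 7.26 ± 1.14 to 12.3 ± 2.22 CPM, a log2 fold change of 0.76, which was 0.41 and no longer called with the length offset (adjusted p = 0.0624). With the replicate block added to the length offset, edgeR called Cd14 higher (adjusted p = 0.0491). Of 28 tested type I interferon-stimulated genes, 9 rose and 4 fell (the same adjusted over the list alone), and the list was not called (median log2 fold change 0.39, camera adjusted p = 0.343). Isg15, a ubiquitin-like antiviral protein gene, rose from 5.73 ± 1.07 to 13.999 ± 3.78 CPM (log2 fold change 1.29, or 0.76 with the length offset). Irf7, an interferon-inducible transcription factor gene, had a log2 fold change of 0.52 (adjusted p = 0.0830, and 0.0430 with the replicate block; without LPS 1 it was called at adjusted p = 0.0338). Of 13 interferon-inducible GTPase genes, 2 rose and 2 fell (the same adjusted over the list alone; camera adjusted p = 0.742). Gbp2 rose from 107 ± 4.91 to 215 ± 21.2 CPM, and Irgm2 fell from 10.3 ± 0.560 to 5.35 ± 1.80 CPM.

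Antigen presentation genes rose. Of 20 tested genes of MHC class I presentation, 13 rose and 1 fell (14 and 1 adjusted over the list alone, 12 and 0 with the length offset), with a median log2 fold change of 0.73 (camera adjusted p = 2.11e-07, and adjusted p = 0.228 with an estimated correlation). The immunoproteasome genes Psmb8 and Psmb10 rose by 1.96 and 1.39 on the log2 scale, Psmb10 from 22.3 ± 1.495 to 58.4 ± 11.03 CPM. H2-Q4 rose by 1.91 from 1.06 ± 0.0554 CPM, in a gene family whose members can share reads. Calr, the most abundant member without a call, had 882 ± 56.2 and 1023 ± 60.5 CPM (adjusted p = 0.0862), and was called without LPS 1 (adjusted p = 0.0105).

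Leukocyte adhesion genes did not move together (2 of 14 rose and 4 fell, 2 and 3 adjusted over the list alone, 3 and 3 with the length offset; camera adjusted p = 0.746). Vcam1, which binds leukocyte integrins, rose from 2036 ± 50.7 to 2941 ± 165 CPM (log2 fold change 0.53, SE 0.0944, adjusted p = 0.00206). Icam1 had 120 ± 5.28 and 135 ± 32.6 CPM and was not called (adjusted p = 0.367). The selectin gene Sele fell from 53.0 ± 1.60 to 38.98 ± 8.39 CPM (adjusted p = 0.0308) and Selp from 576 ± 44.3 to 433 ± 78.4 CPM (adjusted p = 0.0262). The call of Sele ended without each of Vehicle 1, Vehicle 2, Vehicle 3, LPS 2 and LPS 3 (adjusted p up to 0.0976), and that of Selp without each of Vehicle 1, Vehicle 2, LPS 2 and LPS 3 (adjusted p up to 0.108).

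Coagulation and fibrinolysis genes rose as a list. Of 17 tested, 9 rose and 2 fell (9 and 3 adjusted over the list alone), with a median log2 fold change of 0.30 (camera adjusted p = 0.00788, and adjusted p = 0.283 with an estimated correlation). The members that rose most were Procr, the protein C receptor, from 32.6 ± 4.04 to 132 ± 22.5 CPM, Plau, urokinase, from 14.9 ± 1.29 to 41.3 ± 7.30 CPM, and Tfpi2, a protease inhibitor, from 9.95 ± 3.36 to 28.1 ± 10.2 CPM. Thbd, thrombomodulin, rose by 0.72 on the log2 scale from 186 ± 26.3 CPM. F3, tissue factor, had 13.3 ± 0.954 and 13.5 ± 2.02 CPM (adjusted p = 0.943). Vascular tone mediators were not called as a list (10 of 19 rose and 5 fell, the same adjusted over the list alone, 8 and 7 with the length offset; camera adjusted p = 0.194). Edn1, the vasoconstrictor endothelin, fell from 21.02 ± 1.64 to 14.2 ± 4.54 CPM (adjusted p = 0.0447), and its call ended without each of Vehicle 1, Vehicle 2, Vehicle 3 and LPS 3 (adjusted p up to 0.138).

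Lists of metabolic and stress genes were called as well. Of 27 tested oxidative phosphorylation genes, all nuclear-encoded, 23 rose and 1 fell, the same adjusted over the list alone (camera adjusted p = 3.89e-08, and adjusted p = 0.387 with an estimated correlation). The median transcript of this list had 1791 bases, and its median log2 fold change of 0.66 was 0.36 with the length offset, when 20 genes were called higher and 0 lower. Cox5b, a subunit of complex IV, rose by 1.25 on the log2 scale, or 0.72 with the offset. Of 12 mitochondrially encoded mRNAs, a family chosen after its values were seen, 1 was called higher and 3 lower (camera adjusted p = 0.338). With the length offset 1 was higher and 7 lower (camera adjusted p = 5.97e-06, and adjusted p = 0.302 with an estimated correlation). Of 20 glycolysis genes, 12 rose and 2 fell, the same adjusted over the list alone (median log2 fold change 0.41, camera adjusted p = 0.00763, and adjusted p = 0.387 with an estimated correlation). Ldha, lactate dehydrogenase A, rose from 1867 ± 97.4 to 3038 ± 361 CPM, a log2 fold change of 0.70, or 0.40 with the length offset. Pgam1 had 518 ± 32.5 and 519 ± 31.7 CPM and was called lower with the length offset (log2 fold change −0.29, adjusted p = 0.0374). Of 21 oxidative stress genes, 12 rose and 1 fell (12 and 2 adjusted over the list alone, 15 and 2 with the length offset). Their median log2 fold change was 0.69, or 0.37 with the length offset (camera adjusted p = 0.000405, and adjusted p = 0.283 with an estimated correlation). Mt1, a metallothionein, rose from 616 ± 11.4 to 1695 ± 416 CPM, a log2 fold change of 1.46 (0.97 with the length offset), and Nox4, an NADPH oxidase, fell from 19.5 ± 1.90 to 8.44 ± 2.91 CPM. Of 22 immediate early and AP-1 genes, 13 rose and 3 fell, 14 and 3 adjusted over the list alone (median log2 fold change 0.66, camera adjusted p = 0.00763, and adjusted p = 0.387 with an estimated correlation). Ier5 rose by 1.34 and Egr2 by 1.26 on the log2 scale, and Egr1 had 60.0 ± 9.33 and 61.1 ± 5.58 CPM (adjusted p = 0.883).

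Cholesterol synthesis and uptake was the list called lower. Of 22 tested genes, 14 fell and 8 were not called (14 lower and 1 higher adjusted over the list alone), with a median log2 fold change of −0.43, or −0.28 with the length offset, when 10 fell. The camera adjusted p was 0.00135, with adjusted p = 0.357 with an estimated correlation. Idi1, an isoprenoid synthesis enzyme, fell from 32.1 ± 2.70 to 16.4 ± 6.29 CPM, a log2 fold change of −0.96 (SE 0.221, adjusted p = 0.00611). The sterol carrier gene Stard4 fell from 36.4 ± 2.71 to 20.9 ± 2.43 CPM, a log2 fold change of −0.80, or −0.46 with the length offset.

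**Figure D3:**
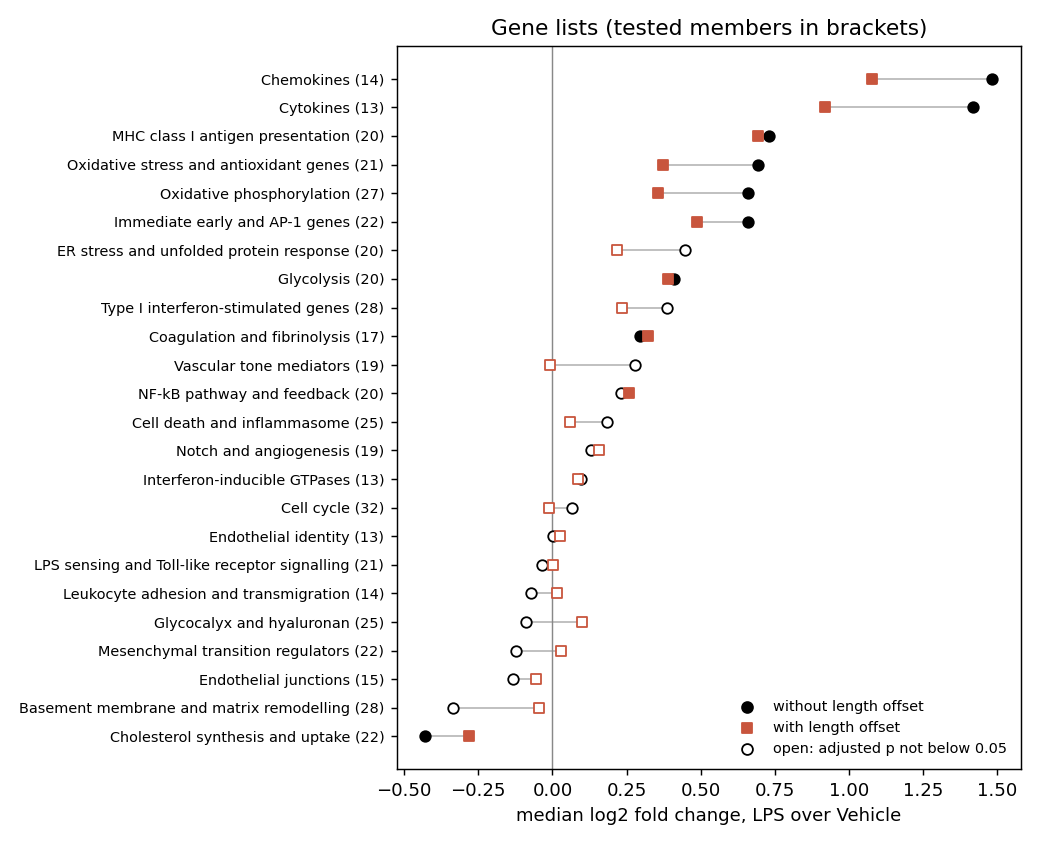
Median log2 fold change of LPS over Vehicle for 24 gene lists, without (black circles) and with the offset for transcript length (red squares); filled symbols have a camera adjusted p below 0.05 and open symbols do not. Chemokines lie highest at 1.48 and cholesterol synthesis lowest at −0.43.

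The remaining lists were not called. Of 28 genes in the list Basement membrane and matrix remodelling, 5 rose and 14 fell (5 and 16 adjusted over the list alone; camera adjusted p = 0.101). With the length offset 9 were called higher and 9 lower, and the median log2 fold change of −0.33 became −0.0447. The list was called lower without LPS 1 (adjusted p = 0.00983). In it Timp1 rose from 1735 ± 135 to 4606 ± 1382 CPM, a log2 fold change of 1.41 (0.88 with the length offset), and Timp3 fell from 2378 ± 212 to 713 ± 380 CPM, both inhibitors of metalloproteinases. Of 25 glycocalyx genes, 7 rose and 11 fell (8 and 12 adjusted over the list alone; camera adjusted p = 0.492), against 11 higher and 5 lower with the length offset. The heparan sulfate carrier Gpc6 fell by 1.65 on the log2 scale. Of 20 genes in the list ER stress and unfolded protein response, 11 rose and 4 fell (12 and 4 adjusted over the list alone, 6 and 1 with the length offset; camera adjusted p = 0.0794, and 0.0473 without Vehicle 3). Of 25 cell death and inflammasome genes, 7 rose and 5 fell (the same adjusted over the list alone, 3 and 3 with the length offset; camera adjusted p = 0.614). Of 32 cell cycle genes, 4 rose and 3 fell (3 and 1 adjusted over the list alone, 5 and 1 with the length offset; camera adjusted p = 0.795). Of 19 Notch and angiogenesis genes, 8 rose and 5 fell (8 and 8 adjusted over the list alone, 9 and 3 with the length offset; camera adjusted p = 0.759). Of 22 mesenchymal transition regulators, 6 rose and 9 fell (the same adjusted over the list alone, 6 and 5 with the length offset; camera adjusted p = 0.499), and the fibronectin gene Fn1 fell from 18727 ± 1407 to 9932 ± 1902 CPM, a log2 fold change of −0.91, or −0.27 with the length offset. Of 15 endothelial junction genes, 2 rose and 6 fell (3 and 6 adjusted over the list alone, 3 and 3 with the length offset; camera adjusted p = 0.417). Gja4, connexin 37, rose by 1.48, and Tjp1, a tight junction scaffold, fell by 1.06, or by 0.51 with the length offset.

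Many endothelial identity genes were at very low levels in both groups. Of 30 such genes, 19 had fewer than 1 CPM in Vehicle, and the median over the 30 was 0.260 CPM. Cdh5, VE-cadherin, had 0.0361 ± 0.0313 CPM in Vehicle and 0.0315 ± 0.0545 CPM under LPS. Pecam1 had 0.482 ± 0.374 and 0.280 ± 0.192 CPM, Tek 0.175 ± 0.129 and 0.0829 ± 0.105 CPM, and Nos3, the endothelial nitric oxide synthase, 0.124 ± 0.136 and 0.159 ± 0.179 CPM; none of these 4 had enough counts for a test. The 8 identity genes with at least 5 CPM in Vehicle were Flt1, Eng, Erg, Klf4, Plvap, Ets1, Gata2 and Cav1, listed here in full. The most abundant of them were Cav1 and Eng, which mesenchymal cells also express. Of 13 tested identity genes, 1 rose and 2 fell, the same adjusted over the list alone, and 3 rose and 3 fell with the length offset (camera adjusted p = 0.892). Klf2, a flow-responsive transcription factor gene, rose from 4.31 ± 0.954 to 9.64 ± 3.35 CPM. Erg and Cav1 fell by 0.60 and 0.35 on the log2 scale; their calls ended without each of Vehicle 1, Vehicle 2 and LPS 3, and that of Cav1 also without Vehicle 3 and without LPS 2 (adjusted p up to 0.0848 and 0.0880).

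Genes of fibroblasts and mural cells were abundant in all libraries. In Vehicle, Col1a1 had 2920 ± 176 CPM, Col1a2 2025 ± 210 CPM, Rgs5 879 ± 54.6 CPM, Pdgfrb 621 ± 9.39 CPM and Acta2 242 ± 15.8 CPM. Of 11 fibroblast markers 4 rose and 3 fell, of 6 tested pericyte markers 0 rose and 3 fell, and of 8 tested smooth muscle markers 1 rose and 2 fell, the same counts as adjusted over each list alone. With the length offset these counts were 3 and 1, 0 and 1, and 1 and 1. Col1a1, Col1a2 and Pdgfrb fell by 0.54, 0.48 and 0.54 on the log2 scale, and none of them was called with the length offset (adjusted p = 0.450, 0.412 and 0.122); the call of Col1a2 also ended without Vehicle 1 and without LPS 2 (adjusted p up to 0.0657). Most markers of leukocytes were near 0. Of 13 macrophage markers the median was 0 CPM in both groups, and the 3 with enough counts for a test were not called by edgeR. Of these, Csf1r had 4.45 ± 0.551 CPM in Vehicle and 5.19 ± 0.754 CPM under LPS (adjusted p = 0.370), and Cd68 0.967 ± 0.270 and 1.13 ± 0.503 CPM (adjusted p = 0.739). The neutrophil markers S100a8 and Camp were called higher, at 1.05 ± 0.546 and 0.859 ± 0.296 CPM under LPS, and Camp lost its call without LPS 2 (adjusted p = 0.0587). The lymphocyte gene Trbc2 was called higher at 0.796 ± 0.401 CPM, and its call ended with the length offset (adjusted p = 0.150) and without each of Vehicle 1, Vehicle 2, LPS 2 and LPS 3 (adjusted p up to 0.190). The 6 red blood cell genes had too few counts for a test. In the remaining lists, 1 of 2 lymphatic, 1 of 2 mesothelial and epithelial and 1 of 1 adipocyte markers were called, all higher and also when adjusted over each list alone: Pdpn, Krt19 and Pparg. The call of Pparg ended with the length offset (adjusted p = 0.0985) and without each of Vehicle 1, Vehicle 2, LPS 2 and LPS 3 (adjusted p up to 0.0861).

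**Figure D4:**
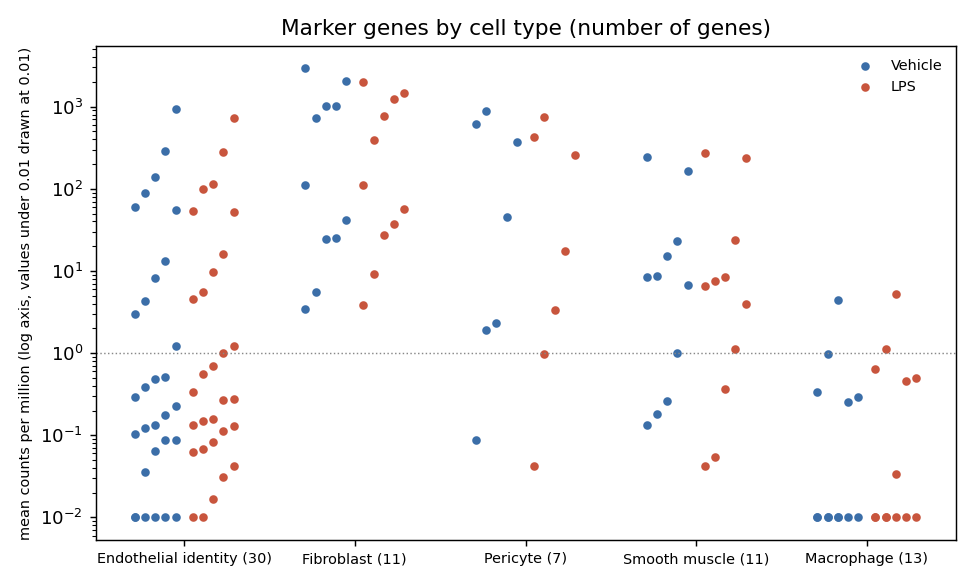
Mean CPM (log axis, values under 0.01 drawn at 0.01) of marker genes in Vehicle (blue) and LPS (red), 1 point per gene and group; the dotted line marks 1 CPM. Of 30 endothelial identity genes, 19 lie below the line in Vehicle, while fibroblast genes such as Col1a1 reach 2920 CPM.

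The 3 cell isolations were compared within the same libraries. In a model with isolation and group, edgeR called 1 gene between isolations, the predicted gene Gm10241 (adjusted p = 0.0300), which was named after its value was seen, and 1339 genes had an unadjusted p under 0.05; DESeq2 called 36 genes, and edgeR 478 without a filter and 4 with the length offset. The 3 LPS libraries lay further apart than the 3 Vehicle libraries: on a principal component that held 78.3% of the variance, LPS 1, 2 and 3 were at 9.76, 40.5 and 54.6, and Vehicle 1, 2 and 3 at −38.5, −39.6 and −26.9. As label checks, Xist had 0 to 4 counts per library, while the Y-linked gene Ddx3y had 1240 to 2737 counts, as male samples have.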

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

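The length offsets, their combinations and the fit without the LPS libraries of isolations 2 and 3 are tests chosen after the data were seen; the other alternatives were planned. Of 109 called genes among the 141 named by the rule and tested, 89 kept their direction and call wherever 17 planned settings tested them. These settings leave aside the threshold of 0.01 and the fit without isolation 2. A gene without a result in a setting was not counted as lost there, and the filter of 1 CPM in 3 libraries tested 134 of the 141. With the transcript-length offset 96 kept their call, and without isolation 2 7 did. The number of lists called higher stayed at 8 or 9 in every fit that left out a library or isolation.

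At the 0.01 threshold 2309 genes were higher and 2223 lower, by construction. With the transcript-length offset, 3172 genes were higher, 1945 lower and 330 at least 2-fold higher. The gene-length offset gave 2288 and 355. With length and GC, 1985 were lower, 346 at least 2-fold higher and 499 at least 2-fold lower. The length offset with the replicate block gave 2214 lower and 315 at least 2-fold higher. Of the calls with the transcript-length offset, 1037 were made only with it; the cause of these counts was not tested. Without the LPS libraries of isolations 2 and 3, with fewer samples, 2033 genes were higher and 2118 lower, 136 and 312 of them at least 2-fold.

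Over the fits that left out a library or an isolation, genes higher ranged from 8 to 4362, genes lower from 0 to 4463, those at least 2-fold higher from 8 to 1204 and those at least 2-fold lower from 0 to 1362. The low ends came from edgeR without isolation 2, where 2587 and 2469 genes had an unadjusted p under 0.05 and DESeq2 called 1543 and 1259; the high ends came without LPS 1. Lists called lower ranged from 1 to 2.

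With an estimated correlation, camera called 1 list higher (chemokines) and 0 lower, where 3 and 0 had an unadjusted p under 0.05; with the length offset it also called 1 and 0. Lists called lower numbered 2 without a filter, 3 with fry and 2 with fry and the replicate block. Lists called higher numbered 8 with camera, 12 with fry and 11 with fry and the block. Lists called with fry but not with camera were nuclear factor kappa B (adjusted p = 0.00167), vascular tone (0.00167), cell death (0.0152) and ER stress (0.0279), higher, and endothelial junctions (0.00167) and mesenchymal transition (0.0201), lower. fry tests whether genes of a list move on balance in 1 direction and does not compare lists. Genes differing between isolations numbered 1, but 2 with library sizes alone, 478 without a filter, 36 with the DESeq2 likelihood ratio test and 4 with the length offset; the cause was not tested.

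Some log2 fold changes turned direction. Pgam1 had −0.29 with the transcript-length offset, −0.32 with the gene-length offset, −0.32 with length and GC and −0.30 with the length offset and block. Tnfaip3 had 0.16 with the transcript-length offset, 0.16 with length and GC and 0.16 with the length offset and block. Cxcl12 had 0.22 with the length offset and block, Col1a2 0.0863 with the gene-length offset, and Tlr2 0.30 without the LPS libraries of isolations 2 and 3. The cause was not tested.

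The replicate block called 3706 genes higher and 3693 lower, 676 and 838 of them at least 2-fold, with 7007 genes shared in direction with the fit without it. Among the named genes reported here the block added the calls of Cd44, Mcm6, Timp2, Unc5b, Irf7 and Rgs5 and ended that of Atf3 (adjusted p = 0.0508); with camera it changed no list, and with fry oxidative phosphorylation (adjusted p = 0.0515) and mesenchymal transition (adjusted p = 0.161) lost their calls. Depth limits the genes near the floor of 0.117 to 0.188 CPM, among them many endothelial identity genes.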

Other observations

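Except for the slope among intron-poor genes and the transcript length of endothelial identity genes, the tests and gene families below were chosen after the result was seen. Genes of protein synthesis and turnover were higher under LPS. Of 80 tested cytosolic ribosomal protein genes 79 were called higher, with a median log2 fold change of 1.17 (camera adjusted p = 1.49e-33, and adjusted p = 0.278 with an estimated correlation), or 0.71 with the length offset, when 77 were called. Of 77 mitochondrial ribosomal protein genes 75 were higher (median 0.82, or 0.52 with the offset), of 37 proteasome genes 33 (0.80, or 0.44) and of 24 Sm and LSm splicing genes 21 (0.82, or 0.63). Each of these 3 families also had adjusted p = 0.278 with an estimated correlation. The median transcript lengths of these 4 families were 1100, 1884, 1883 and 1868.5 bases, against 3197.5 for tested genes, and ribosomal protein genes have many pseudogenes that can share reads. The offset left part of the trend among short genes. With it, all tested genes of 57 to 1084, 1085 to 1707 and 1708 to 2216 bases kept medians of 0.241, 0.138 and 0.0783.

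In 4 families with longer transcripts, collagens, semaphorins and plexins, lysine methyltransferases and Zfp genes, more genes were called lower than higher, with adjusted p = 0.278 with an estimated correlation. Median transcripts had 6048 bases for collagens, 6307 for semaphorins and plexins, 6621 for lysine methyltransferases and 3619 for Zfp genes. Of 35 collagen genes 17 were called lower and 2 higher (median log2 fold change −0.43, camera adjusted p = 0.000202), but with the length offset 7 were lower and 6 higher (median 0.08). Of 25 semaphorin and plexin genes 15 were lower and 0 higher (camera adjusted p = 3.01e-06), and 5 lower with the offset. Of 18 lysine methyltransferase genes 12 were lower and 2 higher (camera adjusted p = 0.000238), and 5 lower with the offset. Of 319 tested Zfp zinc finger genes 98 were lower and 22 higher (camera adjusted p = 0.00013), with a median of −0.27, or −0.14 with the offset, when 53 were lower and 24 higher (camera adjusted p = 0.000786, and adjusted p = 0.0273 with an estimated correlation). Of 18 ephrin and Eph receptor genes 1 was higher and 7 lower, and of 18 zinc carrier genes 2 and 5, and neither family was called (camera adjusted p = 0.0933 and 0.338).

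Log2 fold changes fell by 0.298 per doubling of transcript length across all genes. Among 1578 intron-poor genes, whose genomic span is at most 1.2 times their transcript, the slope was −0.179 (SE 0.0155). Loss of long RNA molecules in the LPS libraries would give such a slope. The SE is over genes, which are not independent replicates, and leaves out the spread between libraries. At equal genomic span the median slope on transcript length was −0.321 over 10 bins of span (−0.45 to −0.0984, SE of their mean 0.0309). This argues against transcription that stops early over long genomic spans. The slopes of the LPS and Vehicle libraries did not overlap (exact permutation p = 0.1, the smallest possible), so library quality and an action of LPS on long mRNAs cannot be told apart, since each LPS library was also an LPS culture. A candidate explanation for part of the called genes is therefore a difference in RNA quality, and the length offset would also remove a true action of LPS on long mRNAs.

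Endothelial identity genes lay near 0 while fibroblast and mural genes were abundant. Those below 1 CPM had a median transcript length of 3974 bases, against 3197.5 for tested genes, a comparison that cannot decide on loss of long transcripts. A long transcript alone need not bring a gene near 0. The 1450 genes of the longest bin, of 6658 to 123179 bases, had enough counts for a test, and Fn1, of 8315 bases, had 18727 CPM in Vehicle. A further test, with a bound of 5 genes, was set after the data were seen. Exactly 5 of the 19 had transcripts no longer than the median of tested genes and were below 1 CPM all the same. This argues against loss of long transcripts for these 5. Of 29 fibroblast, pericyte and smooth muscle markers, 21 had at least 5 CPM in Vehicle. Cultures made up mostly of fibroblast or mural cells may therefore account for the pattern. This count does not weigh genes that go the other way. Among them are the identity gene Erg, at 8.29 CPM in Vehicle, and the selectin genes Selp and Sele, at 576 and 53.0 CPM. Loss of endothelial expression by endothelial cells in culture stays open, as 8 identity genes had at least 5 CPM and no freshly isolated cells were analysed here.

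For chemokine and cytokine genes, which were higher under LPS, the median log2 fold change of the 27 tested genes with the length offset was 1.03 (bootstrap SE 0.314), from 1.42 without it, less than 2 SE above the bound of 0.5 first set, so the trend as part of the change stays open. A further test was added after that outcome: of 10000 random lists matched on length and CPM the 95th percentile of medians was 0.227, which argues against the length trend as the whole cause. Macrophages in the LPS cultures are argued against by the abundant macrophage genes Lyz2, which reached 0.944 CPM in an LPS library, and Tyrobp, C1qa, C1qb and Ptprc, with 0 counts in all libraries, although Csf1r was at 4.45 CPM in Vehicle and 5.19 CPM under LPS, without a call. A trace of neutrophils or lymphocytes stays open, as S100a8 and Camp were called higher with and without the length offset and Trbc2 without it. Their levels were low, however. The 20 markers of these cells had a median of 0.0168 CPM under LPS and reached at most 1.66 CPM in an LPS library. S100a9 had 0 counts, as did Ptprc, a gene of leukocytes in general. These levels argue against neutrophils or lymphocytes as the main source of the change. A response of the cultured cells to LPS is the hypothesis that the comparison of the groups itself addresses. The higher calls of these genes go with it. The length trend also parts the groups, however, and no separate test on other data was made.

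The 10 splits of the 6 libraries into 3 and 3 are too few for a share under 0.05. Every split but the real one also mixes Vehicle and LPS libraries within its groups. A difference between Vehicle and LPS then widens the spread within groups, so 0 called genes in such a split says nothing about chance. For genes called, 1 split, the real one, gave as many as 7150, and the highest other gave 0 with edgeR (48 to 797 genes at an unadjusted p under 0.05) and 0 with DESeq2, which called 7256 in the real split. For genes called at least 2-fold, 1 split gave as many as 1503, and the highest other gave 0. For gene lists, 2 of the 10 splits gave as many as 9, and the highest other gave 9; it set Vehicle 1, Vehicle 2 and LPS 2 against the rest and parted 1 pair. The 3 other splits that part all 3 pairs, as the real one does, gave at most 6 lists and 0 genes.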
